A study of Streptococcus mutans UA159 with 8 samples.

How the data were processed

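The 8 arrays used here were each a 2-colour array of Streptococcus mutans UA159, a bacterium that forms dental biofilms. Biofilms were grown on saliva-coated hydroxyapatite, a mineral surface like that of the tooth, and RNA was taken at 50 h. Per the labels, 4 biofilms were exposed for 60 s, 2 times a day, to 1.5 mg/ml of cranberry proanthocyanidins (PAC, plant polyphenols) in 15% ethanol, and 4 were exposed to 15% ethanol alone as the vehicle. Biofilm RNA was labelled with Cy3 and RNA from a mid-log planktonic culture, the common reference, with Cy5 on every array, so that no dye swap exists. Groups and replicate numbers came from the sample titles. The series design calls the 4 arrays of a group biological replicates. The labelling text of the reference channel calls its RNA biofilm RNA, while the source and the other labels call it planktonic, and the latter was followed.

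The authors deposited 1 spot table per array with mean spot intensity in 2 channels, called A and B, with the local background already subtracted, per the file headers and the values. The same tables hold the deposited local background intensity and the spot area in pixels. They also hold a normalised integrated intensity per channel, which the values show to be a smooth function of spot intensity with dim or rejected spots set to 0, between 983 and 1318 of 9740 spots per array. The deposited series table holds log2 ratios of channel A over channel B computed from those normalised intensities. All 69365 values matched that ratio to within 5e-10. Its column medians were -0.10, -0.09, -0.07 and -0.06 in vehicle 1 to 4 and -0.08, -0.09, -0.09 and -0.08 in PAC 1 to 4, so its columns are near but not centred on 0. The image software, its version, the normalisation method and the genome build are not given in the sources used here.

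The files name the channels by letter and not by dye, so the direction of every ratio is likely rather than stated. Channel A was taken as the biofilm because the labels list the Cy3 biofilm channel first and the deposited ratio is A over B. Channel B was also the more alike of the channels in 15 of 16 pairs of a vehicle and a PAC array, and in 16 of 16 after sub-grid medians were removed, as a common reference would be. In a check chosen after seeing the data, with channel A alone and sub-grid medians removed, 10 genes differed between groups at an adjusted p under 0.05 in limma, and with channel B alone 0 genes did, against 331 and 128 genes at an unadjusted p under 0.05. In the planned fit of channel A alone, with quantile normalisation, 0 genes were past that threshold in limma (219 at an unadjusted p under 0.05). The count for channel A thus depends on the processing.

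Each array holds 9740 spots in 48 sub-grids, 12 rows by 4 columns, with 1948 probes of 70 bases printed 5 times each in 1 sub-grid. They represent 1947 loci. Gene names came from the files and from the RefSeq table of assembly ASM746v2, in which 1837 loci were found by older locus tag and 110 were not. No coordinates are given because the files name no build. The files list more than 1 matching gene for 20 probes, and none of these belongs to a gene named here. Spots with the image software's flags B or C in both channels and intensities above 0 were used, between 9332 and 9521 spots per array.

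Log2 ratios of the deposited background-subtracted intensities were normalised within each array by loess on mean log intensity (limma 3.58.1 in R 4.3.3, span 0.3, 4 iterations). Spots of a probe were averaged, then probes of a gene. Genes measured on at least 2 arrays of each group, 1910 in all, were tested with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over these genes and a threshold of adjusted p under 0.05. Gene lists, 34 fixed before the data were examined, were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. Camera used the 1878 genes measured on all 8 arrays. One locus was dropped from the purine list because its annotated product contradicted the list. Biofilm over reference was described without a test, because gene-specific dye effects cannot be separated from it.

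The genes named were set by a rule made before the data were examined. They are the genes past the threshold whose groups do not overlap, the 20 genes with the smallest p where fewer than 10 pass, every measured member of the glucan list, the 4 members with the smallest p of each list past the threshold, and the 5 highest and 5 lowest genes against the reference. Genes named outside that rule are said to be so.

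Alternatives fixed before the data were examined covered background correction (normexp with offset 50), 50 added to both channels, median centring, a separate loess in each of the 48 sub-grids, scaling between arrays, the biofilm channel alone, a filter on dim genes, the median of spots, ignoring flags, the authors' values, trended and robust eBayes, array weights, a replicate block, slide series, leaving out each array, 2 other thresholds and 2 other list tests. Numbers on the slides, taken from the file names, put vehicle 1 and 2 and PAC 1 and 2 in series 1, vehicle 3 and 4 and PAC 3 in series 2, and PAC 4 in series 3. With slide series as a block, PAC 4 is alone in its series and adds nothing to the difference between groups. A smooth surface over spot rows and columns after loess (span 0.1), and combinations of 2 or more alternatives, were chosen after seeing the data. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9.

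The procedure was tested on simulated arrays with the real sub-grid shifts, with 100 of 1910 genes changed by 0.5 (log2) and 100 by 1. A further 9 genes of the glycolysis list were raised by 0.5, and 5, 5 and 7 of them were called with loess, sub-grid loess and the smooth surface, as true calls. The list's adjusted p in camera was 0.00780, 0.0448 and 0.0117, and 0 other lists were past the threshold. Noise was drawn independently for each gene, whereas the estimated inter-gene correlation was up to 0.37 in the real lists past the threshold. The simulation therefore does not show how many lists would pass falsely in the real data. With loess, 40% of the 100 genes changed by 0.5 (log2) and 99% of the 100 changed by 1 were called, and 3 of 147 calls were false. With sub-grid loess the shares were 40% and 96%, with 22 of 163 calls false (13.5%), and with the smooth surface 72% and 100%, with 18 of 197 calls false (9.14%). Both false shares lie above the 5% that the threshold aims at, in 1 simulated data set. The noise SD was the same for every simulated gene. With 147 calls the adjusted threshold is also easier to pass than with the 4 calls of the real data. There SMU.1070c (0.89) and SMU.1985 (-0.78) were not past it (limma adjusted p 0.0820 and 0.110). The shares called therefore do not show how many changed genes would be found in the real data.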

Results

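The transcriptome of S. mutans biofilms exposed to cranberry PAC was compared with that of biofilms exposed to the ethanol vehicle, 4 arrays each, with a planktonic culture as the common reference on every array. Median background-subtracted spot intensity lay between 1250 and 1933 in the likely biofilm channel and between 1216.5 and 2265 in the reference channel, against median local backgrounds of 70 to 102 and 54 to 81. Between 95.8% and 97.8% of the spots of an array were used. Correlations of log2 ratios across genes between any pair of arrays ranged from 0.936 to 0.989.

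The first comparison asks which genes differed in biofilms exposed to PAC. Directions here and in all that follows take channel A as the biofilm, which is likely rather than stated, and with the channels the other way every difference and ratio would change sign. A pair of neighbouring genes stood highest. SMU.941c, a hypothetical protein, rose 2.57-fold, from a log2 ratio to the reference of -2.99 ± 0.12 (SD, n = 4) in vehicle to -1.63 ± 0.29 (SD, n = 4) in PAC biofilms, a difference of 1.36 with an SE of 0.14 and an adjusted p of 0.00367 in limma. SMU.940c, annotated as a putative hemolysin III, rose 2.05-fold (log2 difference 1.03, SE 0.14, limma adjusted p 0.0181). SMU.1550c, an integral membrane protein, rose 1.53-fold (0.61, SE 0.10, limma adjusted p 0.0486). SMU.671 (citZ), citrate synthase, the entry enzyme of the citrate pathway to glutamate, fell 1.52-fold (-0.60, SE 0.10, limma adjusted p 0.0486).

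These 4 of 1910 genes, 3 higher and 1 lower, were past the threshold, and 278 genes (14.6%) had an unadjusted p under 0.05. In 184 genes (9.63%) the 4 PAC arrays all lay on one side of the 4 vehicle arrays, where chance gives 2.86% on average over splits of the arrays. Genes on the same arrays vary together, so a single split can lie far from that average. The share was not computed for other splits. The log ratios also varied with position on the slide, with sub-grid medians of the PAC minus vehicle difference from -0.16 to 0.27, and the count of genes depended on how that was treated. With a separate loess in each sub-grid 55 genes were past the threshold, 31 higher and 24 lower, among them 3 of the 4, and with a smooth surface over the slide 219 were (97 higher). SMU.671 differed by -0.19 with sub-grid loess (limma adjusted p 0.395) and by -0.52 with the smooth surface (limma adjusted p 0.00338). With log ratios scaled between arrays 2 genes were past it, both higher, and SMU.940c (0.76, limma adjusted p 0.148) was not, nor was it with the authors' values (0.77, limma adjusted p 0.0604).

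**Figure D1:**
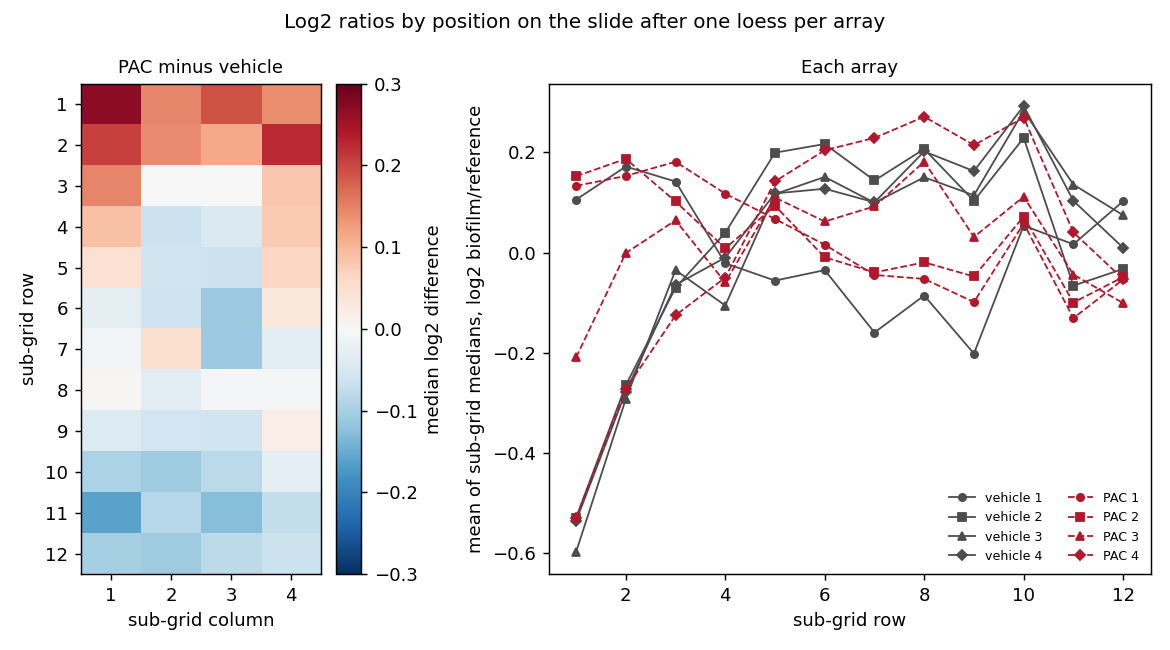
Left, median log2 difference (PAC minus vehicle) of the genes in each of the 48 sub-grids of the slide. Right, mean of the sub-grid medians of log2 biofilm over reference in each sub-grid row, for each of the 8 arrays; the means of the differences were 0.18 in rows 1 and 2 and -0.09 in rows 10 to 12.

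The other 16 of the 20 genes with the smallest p were not past the threshold, with limma adjusted p from 0.0559 to 0.0749, although the groups did not overlap in any of them. Of the 16, 7 had higher values in PAC and included SMU.1553c (0.62) and SMU.1551c (0.58), near SMU.1550c, and SMU.1069c (0.55). Among them were also SMU.127 (adhA), a subunit of acetoin dehydrogenase (0.56), SMU.1810 (scnE, 0.48) and SMU.1811 (scnF, 0.51), annotated as components of a bacteriocin operon, and SMU.1295 (add), adenosine deaminase (0.43). Those with lower values included SMU.270 (ulaA), the permease of an ascorbate phosphotransferase system (-0.50), SMU.857, a putative uracil permease (-0.49), SMU.856 (pyrR), the regulator of pyrimidine genes (-0.51), and SMU.1409c, a putative transcriptional regulator (-0.50). SMU.2098 (argS), the arginyl-tRNA synthetase (-0.42), SMU.2049c, an rRNA methyltransferase (-0.42), and SMU.118c, a putative esterase (-0.51), were lower as well. The remaining genes, SMU.750c (-0.57) and SMU.498 (comF, -0.55), came from dim probes, of which the authors' processing kept 0 spots in either group. The filter on dim genes also removed SMU.1553c, SMU.1551c, SMU.1810, SMU.1811, SMU.270, SMU.1409c and SMU.856, whose spots the authors' processing kept. It removed SMU.1550c as well. With sub-grid loess, 9 of the 16 were past the threshold and SMU.2098 changed sign, to 0.0757. Values of the remaining 6 were then closer to 0, at 0.12 for SMU.1069c, 0.27 for SMU.1551c, -0.34 for SMU.750c, -0.22 for SMU.498, -0.28 for SMU.856 and -0.21 for SMU.118c.

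**Figure D2:**
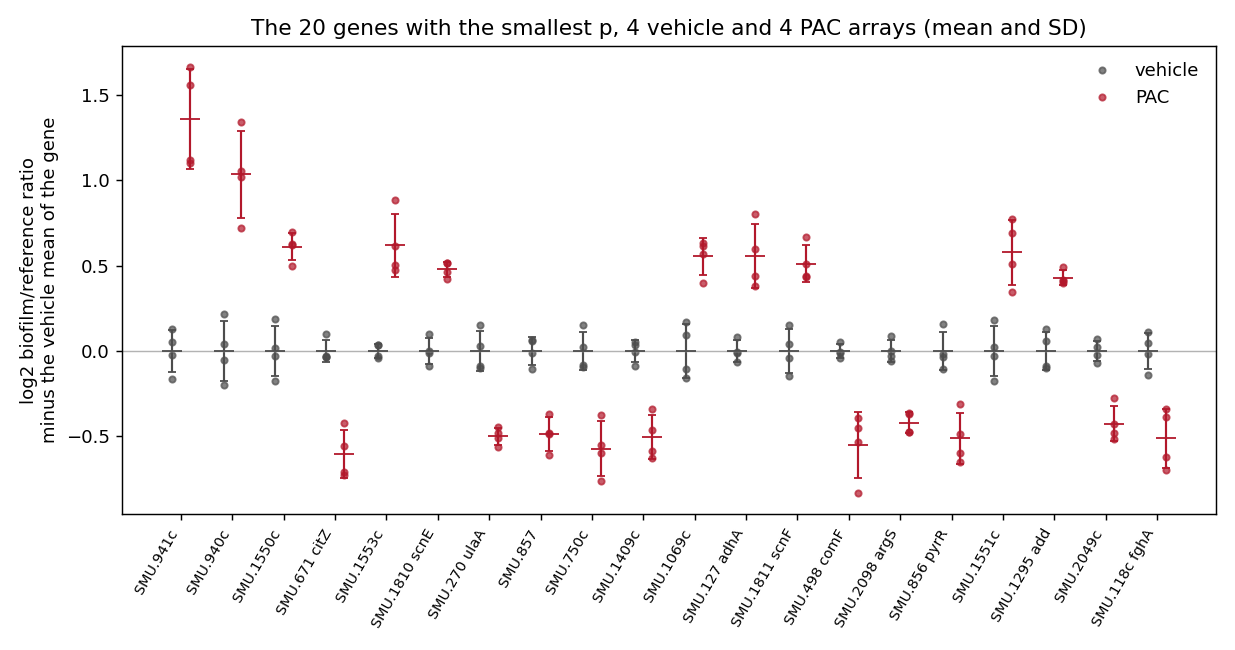
Log2 biofilm over reference ratio of the 20 genes with the smallest p, minus each gene's vehicle mean, in the 4 vehicle and 4 PAC arrays (points), with mean and SD (bars). The PAC arrays of SMU.941c and SMU.940c lie highest, and in all 20 genes the groups do not overlap.

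The count of genes past the threshold in limma was 99 with a replicate block (46 higher, 53 lower). With slide series as a block, where PAC 4 adds nothing, the count was 47. It was 0 within series 1 (128 genes at an unadjusted p under 0.05). With 1 array left out it lay between 1 and 8: 8, 1, 2 and 1 without vehicle 1 to 4, and 2, 1, 1 and 5 without PAC 1 to 4. SMU.941c was past the threshold in all 8 fits without 1 array. SMU.940c was not without vehicle 2 (limma adjusted p 0.101), vehicle 4 (0.0617), PAC 2 (0.0982) or PAC 3 (0.0502). SMU.671 was past it without vehicle 1 (0.0382) and without PAC 4 (0.0369), and SMU.1550c without vehicle 1 (0.0469), and neither was without any other array.

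The second comparison asks whether genes of known function moved together. Of 34 lists, 6 were past the threshold in camera. Pyrimidine synthesis fell, with all 9 measured genes lower, a median log2 difference of -0.23 and an adjusted p of 0.000942 (0.309 with an estimated correlation). Counting over all genes, 0 of its members were past the gene threshold, and adjusted over the list alone 3 fell, SMU.857, SMU.856 (pyrR) and SMU.858 (pyrB), aspartate carbamoyltransferase (-0.37). SMU.1223 (pyrDB), dihydroorotate dehydrogenase, had -0.35. With sub-grid loess SMU.856 had -0.28 and SMU.858 -0.15. The median of the pyrimidine list was -0.38 with sub-grid loess and -0.15 with scaling. Genes of oxidative stress rose, with all 10 higher, a median of 0.28 and an adjusted p of 0.000942 (0.354 with an estimated correlation). Without vehicle 1 the median was 0.17 (adjusted p 0.0169). Among them SMU.924 (tpx), thiol peroxidase, was the 1 member past the threshold adjusted over the list alone (0.37), and values were 0.53 for SMU.540 (dpr), a peroxide resistance protein (0.32 without vehicle 1 and 0.27 with sub-grid loess), 0.50 for SMU.463 (trxB), thioredoxin reductase (0.27 with sub-grid loess), and 0.29 for SMU.1117 (nox), NADH oxidase.

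Arginine, glutamine and glutamate synthesis fell, with 11 of 13 genes lower. Over the 10 of them measured on all 8 arrays the median was -0.15 and the adjusted p 0.0118 (0.309 with an estimated correlation). SMU.671 (citZ) was past the threshold over all genes, and adjusted over the list alone 2 fell, SMU.671 and SMU.672 (icd), isocitrate dehydrogenase (-0.61); both belong to the citrate branch, as does SMU.670 (acnA), aconitase (-0.29), while SMU.366 (gltD), glutamate synthase, had -0.21. With sub-grid loess SMU.671 had -0.19 and SMU.672 -0.22 (limma adjusted p 0.395 and 0.227). With the smooth surface they had -0.52 and -0.50 (limma adjusted p 0.00338 and 0.00505), and 4 members of the list fell past the threshold over all genes. Competence and natural transformation fell, with 12 of 14 genes lower. Over the 13 measured on all 8 arrays the median was -0.20 and the adjusted p 0.0112 (adjusted p 0.715 with an estimated correlation). That median was -0.12 without vehicle 3 (adjusted p 0.0230) and -0.0865 with normexp (adjusted p 0.0241). Adjusted over the list alone 5 fell, among them SMU.1985 (-0.78), SMU.1987 (-0.55) and SMU.1983 (-0.47), which encode the ComYB, ComYA and ComYD proteins of DNA uptake, and SMU.626 (-0.44), a competence protein. With sub-grid loess SMU.1987 had -0.32 and SMU.626 -0.28. The F-type ATPase, which pumps protons out of the cell, rose, with all 8 genes higher, a median of 0.18 and an adjusted p of 0.0112 (0.554 with an estimated correlation). No member passed alone, and SMU.1531 (0.37), SMU.1532 (0.34), SMU.1528 (0.22) and SMU.1533 (0.18) had the smallest p. With sub-grid loess SMU.1531 had 0.14, SMU.1532 0.14 and SMU.1533 0.12.

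The genomic island TnSmu1, an integrated mobile element, fell, with 31 of 34 genes lower. Over the 33 measured on all 8 arrays the median was -0.20 and the adjusted p 0.00219 (adjusted p 0.796 with an estimated correlation). Adjusted over the list alone 1 fell, SMU.196c, a putative transfer protein (-0.58); SMU.197c (-0.52), SMU.210c (-0.51) and SMU.209c (-0.44) followed. With sub-grid loess SMU.196c had -0.0803 (SE 0.19, limma adjusted p 0.840) and SMU.209c -0.19. This direction depended on the scaling: with log ratios scaled between arrays the list was past the threshold the other way (median 0.36, adjusted p 7.45e-05). It was -0.13 without vehicle 3 (adjusted p 0.0230), and without vehicle 4 it was -0.10 and not past the threshold (adjusted p 0.0526). No list was past the threshold with an estimated correlation, where 3 of 34 had an unadjusted p under 0.05. With sub-grid loess the F-type ATPase (median 0.13, adjusted p 0.133), competence (-0.25, 0.0819) and the arginine list (-0.17, 0.0540) were not past it, and the other 3 were. The CRISPR and cas genes (-0.27, adjusted p 0.00839) and pyruvate conversion (0.16, adjusted p 0.0294) then were as well, of which the CRISPR and cas genes also with the smooth surface (-0.24, adjusted p 0.00566). With an estimated correlation neither was, with an adjusted p in camera of 0.419 for both with sub-grid loess. For the CRISPR and cas genes it was 0.649 with the smooth surface. Within slide series 1 the median of TnSmu1 was -0.0431 (adjusted p 0.296 in camera), against -0.53 within series 2. Series 2 has 1 PAC array, so no test is given there, and the difference between series was not tested. The adjusted p in camera was 0.0687 for the arginine list within series 1, and 0.0684 for competence with slide series as a block. Within series 2 the medians were 0.0221 for the ATPase and -0.12 for competence. The ATPase was also not past the threshold with median centring (median 0.0564, adjusted p 0.269) or with the authors' values (adjusted p 0.120), oxidative stress with scaling (median 0.18, adjusted p 0.0820) and competence with dim genes left out (median -0.0747, adjusted p 0.301). With array weights all of these lists but TnSmu1 were not past it (adjusted p 0.0832 to 0.0844), and the median of oxidative stress was 0.13.

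**Figure D3:**
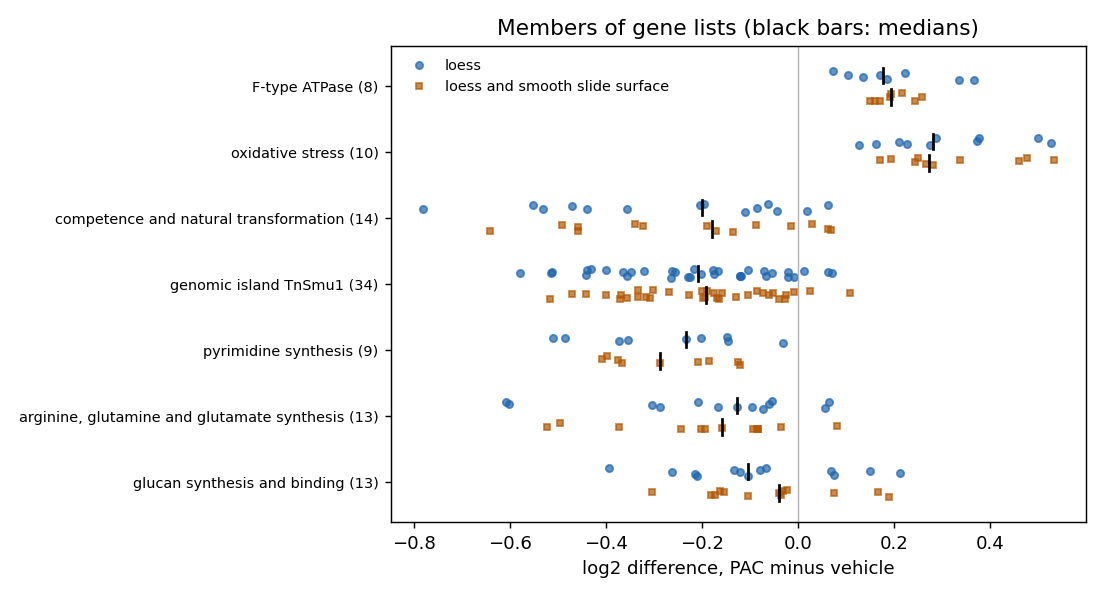
Log2 difference (PAC minus vehicle) of each measured gene of the 6 lists past the threshold and of the glucan list, after loess (circles) and after loess with a smooth slide surface (squares), with the number of genes in parentheses and medians of the genes shown as black bars. All 9 pyrimidine genes lie below 0 and all 10 oxidative stress genes above it.

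The glucan synthesis and binding list holds genes that make or bind sucrose-derived polymers of the biofilm matrix. SMU.22 (pcsB) in it is annotated both as the putative secreted antigen GbpB/SagA and as a putative peptidoglycan hydrolase. The list also holds a dextranase, fructan hydrolases, a dextran glucosidase and a sucrose phosphorylase, so its median mixes synthesis and breakdown. It was not past the threshold as a list (4 of 13 genes higher, median -0.11, adjusted p 0.260 in camera). The median was -0.0208 with sub-grid loess, -0.0403 with the smooth surface and -0.17 without vehicle 1. Adjusted over the list alone 1 fell, SMU.1396 (gbpC), a glucan-binding protein (-0.39, SE 0.11), which was not past the threshold over all genes (limma adjusted p 0.120). With the smooth surface SMU.1396 was past it over all genes (-0.31, limma adjusted p 0.0237). The filter on dim genes removed SMU.1396. The glucosyltransferases had differences of -0.26 (SE 0.17) for SMU.1004 (gtfB), 0.15 (SE 0.10) for SMU.1005 (gtfC) and -0.07 (SE 0.08) for SMU.910 (gtfD). The authors' processing kept 2 spots of SMU.1004 in each group, so its probe was dim, and its value was -0.019 with sub-grid loess, -0.40 without vehicle 2 and -0.14 without vehicle 3. Values were 0.07 for SMU.2112 (gbpA), -0.08 for SMU.22 (pcsB), -0.12 for SMU.772 (gbpD), 0.21 for SMU.883 (dexB), -0.11 for SMU.2042 (dexA) and 0.07 for SMU.881 (gtfA). The fructan genes SMU.2028 (sacB), SMU.79 (fruB) and SMU.78 (fruA) had -0.21, -0.21 and -0.13. Signs of SMU.2112, SMU.22, SMU.2042, SMU.881 and SMU.78 turned with sub-grid loess, which also gave 0.0347 for SMU.1005, -0.0208 for SMU.910, -0.0743 for SMU.772 and -0.10 for SMU.79. Without vehicle 1 SMU.883 had 0.0946, SMU.2112 0.19, SMU.881 -0.0806, SMU.2042 -0.17, SMU.772 -0.19 and SMU.910 -0.0427, and without vehicle 4 SMU.1005 had 0.0881 and SMU.910 -0.10. SMU.2112 had -0.0620 without PAC 2, SMU.22 -0.0162 without PAC 4 and -0.15 without PAC 3, SMU.881 0.20 and SMU.772 -0.0757 without vehicle 2, and SMU.2042 -0.0621 without PAC 1.

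The third description sets vehicle biofilms against the planktonic reference. Genes of TnSmu1 were far above it, with a median log2 ratio of 5.79 (55.5-fold) over 33 genes, 26 of them at least 2-fold above it on all 4 arrays. The 5 highest genes of the array were SMU.213c (7.50 ± 0.38, SD, n = 4), SMU.201c (7.28), SMU.211c (7.26), SMU.206c (7.19) and SMU.202c (7.10), all of that island. The CRISPR and cas genes, a defence against phage, had a median of 3.88, mutacins, which are bacteriocins, 3.49, and purine synthesis 2.26. Metal transport had 1.78, heat shock proteins and Clp proteases 1.25, and the glucan list 0.22. The lowest genes were SMU.962, a putative dehydrogenase (-4.21 ± 0.22, SD, n = 4), SMU.961 (-3.92), SMU.936 and SMU.933, parts of amino acid ABC transporters (-3.63 and -3.41), and SMU.1438c, a putative protease (-3.44). The mutanobactin island TnSmu2 had a median of -2.28, tryptophan synthesis -1.47, pyruvate conversion to acetate, formate and ethanol -1.22 and oxidative stress -1.16. In all, 218 of 1889 genes were at least 2-fold above the reference and 154 at least 2-fold below it on all 4 vehicle arrays, and with the authors' values 157 and 174 of 1736 genes were. With the channels the other way TnSmu1 would lie 55.5-fold below the reference, the 5 highest genes would be the 5 lowest and the reverse, and 154 genes would be above it and 218 below.

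**Figure D4:**
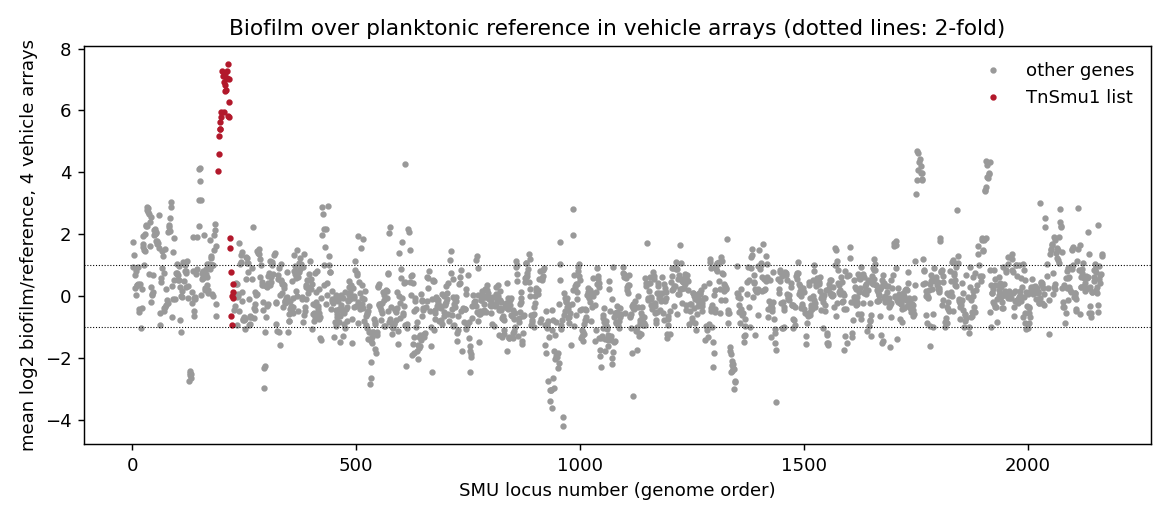
Mean log2 biofilm over reference ratio in the 4 vehicle arrays for each gene, in order of locus number, with the TnSmu1 list in red and dotted lines at 2-fold. Genes of the island reach 7.50, above all others.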

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

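All tests in this part except those of genome neighbours in sub-grids, of 50 added to the channels, of GC-matched lists and of the counts of genes and lists in other splits were chosen after the result was seen. There were 6 values that stood apart from the other 3 arrays of their group by Dixon's test. Vehicle 2 was at 0.62 for SMU.671 and at 6.58 for SMU.210c, PAC 3 at -0.52 for SMU.1295, vehicle 1 at 0.85 for SMU.2042, PAC 1 at -0.64 for SMU.79 and vehicle 4 at 0.57 for SMU.1533. Chance alone marks about 1 in 20 groups, which is 6.1 of the 122 groups tested.

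The PAC minus vehicle differences followed slide position: the SD of the 48 sub-grid medians was 0.102, against at most 0.0485 in 1000 random reassignments of the genes. Of the 35 splits of the 8 arrays into groups of 4, 15 had at least the SD of the real one, itself included, the highest other at 0.247, as a gradient of printing or hybridisation unrelated to treatment would give. The split of slide series 1 from the other arrays had 0.209. Operons printed together would not account for it, since 2.57% of genome neighbours shared a sub-grid.

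Of the 35 splits of the 8 arrays into groups of 4, 3 gave as many genes as the real one, so chance is not excluded for the 4 genes. The others were vehicle 1 and 3 with PAC 1 and 3 against the rest (6 genes) and vehicle 1 with PAC 1, 2 and 3 against the rest, the highest other at 345, which points to a structure of the arrays. Both kept the arrays numbered 1 on one side. The split with 345 genes also had the highest SD of sub-grid medians (0.247). It gave 0 genes with the smooth surface as well as with sub-grid loess, which points to slide position for that split. The splits do not take replicate numbers into account, and the real split with a replicate block gave 99 genes. The split with 345 genes gave 0 with sub-grid loess, where the real split alone (1 of 35) gave 55 and the highest other 3. With the smooth surface, itself chosen after seeing the data, the real split alone (1 of 35) gave 219 and the highest other 23. A share of 1 of 35 is the smallest that these splits can give, and it takes the arrays as unpaired. In these normalisations, however, r was over 0.1 for every replicate number. Only 8 splits part every number, too few for a share under 0.05, so with the numbers kept apart chance is not excluded for these counts. The other 7 of the 8 gave 0 genes, in these normalisations and in the main one. For the 6 lists, 15 of the 35 splits gave as many and the highest other was 10, so chance is not excluded there.

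SMU.940c and SMU.941c were higher in PAC. A slide gradient is argued against by sub-grid loess, under which the differences were at least 7.04 times their SE. In the reference channel alone the differences were -0.12 for SMU.940c and 0.13 for SMU.941c (mean 0.0016), against 0.93 and 1.15 in the likely biofilm channel. Dim spots are argued against by an intensity percentile of 72.7 or more. An effect of PAC on the pair remains as a hypothesis.

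TnSmu1 lay far above the planktonic reference. With 50 added to both channels its median log2 ratio was 5.29. This test could hardly have come out otherwise with so bright a signal in the other channel, so nothing is concluded from it. The island's median reference intensity after background subtraction was 206, against a median local background of 70 on the vehicle arrays. Its reference signal was thus low but above background at the median. The median percentile was 9.40 in the reference channel and 90.0 in the other. Of 1000 lists matched on probe GC 0% reached its median, the highest at 0.54, which argues against GC bias, while dye effects of single genes cannot be separated without a dye swap. Whether the island was more transcribed or present in more copies in these biofilms, or the reference culture was unusual, was not tested.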

How the results depend on the processing

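The alternatives with a smooth slide surface, within slide series 2, with the authors' values and flags applied, and with any pair or more of choices combined were chosen after seeing the data; the others were planned. The number of genes past the threshold (4, of which 3 higher) was 3 or 4 with normexp, 50 added, dim genes left out, flags ignored, trended and robust eBayes or a 1.5-fold minimum. With dim genes left out SMU.1550c was not tested. The count was 9 with median centring, 12 with the median of spots, 2 with scaling between arrays (both higher), 2 with the authors' values, with or without flags applied, 0 with the biofilm channel alone (limma, 219 genes at an unadjusted p under 0.05), 404 with array weights (211 higher), 39 at an adjusted p under 0.1 (13 higher), 47 with slide series as a block (17 higher) and 0 within series 1. It was 55 with sub-grid loess, 219 with the smooth surface (97 higher), 39 with sub-grid loess and scaling, 21 with sub-grid loess and slide series as a block and 0 with sub-grid loess within series 1 (194 at an unadjusted p under 0.05). Leaving out 1 array gave 1 to 8, and with sub-grid loess 13, 22, 9 and 40 without vehicle 1 to 4 and 8, 7, 2 and 13 without PAC 1 to 4. The cause was not tested, except that fewer arrays were used within a series.

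Combinations with another normalisation were counted as well. With a replicate block the count of genes was 103 with normexp, 103 with 50 added, 48 with median centring, 36 with scaling, 96 with flags ignored, 24 with the authors' values and flags applied, 73 with the median of spots, 332 with the smooth surface and 53 with sub-grid loess and scaling. With slide series as a block it was 58, 58, 19, 8, 21, 13 and 62 in the first 7 of these, and within series 1 it was 0 in limma in all 7, with 111 to 154 genes at an unadjusted p under 0.05. Sub-grid loess on the authors' values gave 4 genes (10 with a replicate block, 0 with slide series as a block and 0 within series 1, with 341 and 216 genes at an unadjusted p under 0.05), and sub-grid loess with 50 added gave 58 (105, 31 and 0, the last with 211). Lists past the threshold were 7 and 5 in this pair. Without 1 array at a time the counts ranged from 1 to 6 with normexp and with 50 added, 0 to 14 with median centring, 0 to 5 with scaling, 1 to 8 with flags ignored, 1 to 4 with the authors' values and flags applied, 1 to 7 with the median of spots, 0 to 4 with sub-grid loess on the authors' values and 9 to 34 with sub-grid loess and 50 added.

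The number of lists past the threshold (6) was 12 with scaling (7 higher, 5 lower, against 2 and 4), 5 with median centring (1 higher, 4 lower), 1 with the biofilm channel alone, 2 with array weights, 2 with fry, 2 with sub-grid loess within series 1, 0 with an estimated correlation and 0 with sub-grid loess and an estimated correlation (3 and 2 of 34 at an unadjusted p under 0.05); with 1 array left out it was 6 to 9. The glucan list was past it in 0 of 32 alternatives. The 372 genes 2-fold from the reference ranged from 274 (dim genes left out) to 384 (median centring), and from 379 to 436 without 1 vehicle array. With the authors' values 157 were above the reference and 174 below (331), against 218 and 154.

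Arrays with the same replicate number deviated together in 3 of 4 numbers and not in number 2 (r across genes 0.64, -0.09, 0.58 and 0.50), so the numbers were not taken to pair the samples, which would need an r over 0.1 in every pair after the main normalisation. With sub-grid loess r was 0.25, 0.17, 0.52 and 0.29 (0.33, 0.20, 0.60 and 0.42 with the smooth surface), over 0.1 in every pair, and every PAC array correlated best with the vehicle array of its own number with sub-grid loess (3 of 4 with the smooth surface), a hint from the data of shared variation that the labels do not explain. A replicate block gave 99 genes, and 80 with sub-grid loess.

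Signs turned in these cases. With scaling, SMU.1117 was at -0.10, SMU.196c 0.0681, SMU.197c 0.17, SMU.2042 0.0215, SMU.209c 0.36, SMU.210c 0.34 and TnSmu1 0.36. With sub-grid loess, alone or with a replicate block, SMU.2042 was at 0.13, SMU.2098 0.0757, SMU.2112 -0.23, SMU.22 0.0256, SMU.78 0.0462 and SMU.881 -0.0605. With sub-grid loess and scaling, SMU.1005 was at -0.0032, SMU.1117 -0.13, SMU.196c 0.52, SMU.197c 0.0767, SMU.2042 0.19, SMU.2098 0.18, SMU.209c 0.55, SMU.210c 0.43, SMU.22 0.015, SMU.78 0.0607 and TnSmu1 0.32. With sub-grid loess and slide series as a block, SMU.1004 was at 0.0338, SMU.2042 0.0975, SMU.2098 0.0338, SMU.2112 -0.20, SMU.22 0.0387, SMU.78 0.0491 and SMU.881 -0.0343, and within series 1 SMU.1005 was at -0.20, SMU.2042 0.10, SMU.2098 0.0398, SMU.2112 -0.0961, SMU.22 0.033 and SMU.78 0.0901. Within series 2, SMU.2112 was at -0.0346, SMU.22 0.11 and SMU.881 -0.0206. SMU.2112 was at -0.17 with the smooth surface, SMU.22 at 0.0054 with slide series as a block, SMU.881 at -0.0694 with array weights, and SMU.1005 at -0.34 and SMU.910 at 0.0319 with the biofilm channel alone. Without 1 array SMU.2112 ranged from -0.062 to 0.19 (below 0 without vehicle 3, PAC 1 or PAC 2) and SMU.881 from -0.0806 to 0.20 (below 0 without vehicle 1). The cause was not tested.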

Other observations

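The test of adjacent genes was set before its result was seen, and the other tests and the genes named in this part were chosen after. Among the 55 genes past the threshold with sub-grid loess, 46 were also past it with the smooth slide surface, in the same direction. All gene values in this paragraph are with sub-grid loess. Higher in PAC were SMU.128 (adhB) and SMU.127 (adhA), annotated as subunits of acetoin dehydrogenase (1.06, SE 0.16, and 0.50), SMU.1322 (budC), acetoin reductase (0.40), and SMU.944 (thyA), thymidylate synthase (0.52). Lower were SMU.2118 and SMU.2119 (opuCc and opuCd), parts of an osmoprotectant transporter (-0.34 and -0.63), SMU.2109 (mdeA), a putative multidrug efflux pump (-0.41), SMU.2071 (nrdG), the activating protein of the anaerobic ribonucleotide reductase (-0.52), and the pyrimidine genes SMU.1224 (pyrK, -0.51) and SMU.1221 (pyrE, -0.41). SMU.1221 was not past the threshold with the smooth surface (limma adjusted p 0.226), while the others named here were.

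One hypothesis was that genes transcribed together changed together. This paragraph uses the loess over the whole array unless another normalisation is named. Over 1860 pairs of adjacent genes printed in different sub-grids the mean product of standardised differences was 0.436, against at most 0.0674 in 1000 shuffles, which is consistent with shared transcription. Of 1907 windows of 4 genes, 7 exceeded all but 5% of the shuffles' extremes. These shuffles take genes as independent, which neighbours were not, and windows were not counted in other splits of the arrays. The 7 windows are therefore a description and no test of an effect of PAC. They covered SMU.938 to SMU.943c, where SMU.940c and SMU.941c carried the signal, SMU.1067c to SMU.1070c (mean 0.57), which include an ABC transporter, SMU.1550c to SMU.1553c (0.58), and the comY region from SMU.1981c to SMU.1987, with means of -0.61 and -0.57. With sub-grid loess SMU.1550c to SMU.1553c had 0.57, 0.27, 0.0677 and 0.43, while their mean with the smooth surface was 0.59.

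Another hypothesis concerns the chromosome at large. Ratios of vehicle biofilm to reference fell with distance from the replication origin, with Spearman's rho of -0.35 across 1820 genes, which are not independent replicates, leaving out 4 lists of islands, cas genes and mutacins. Distance was counted in genes in order of locus number around a circle, with the origin taken at the first locus, because no coordinates were used. The median was 0.37 in the 455 genes nearest the origin and -0.32 in the 455 farthest from it. Shuffles of blocks of 20 adjacent genes reached this with a two-sided p of 0.000999, the smallest that 1000 shuffles can give, which argues against chance placement of operons. Rotations of the gene order gave as low a value in 9.8% of cases; this test could not decide, because a rotation by a few genes keeps a gradient. In the PAC arrays rho was -0.30 (as low in 11.7% of rotations). Across genes PAC minus vehicle had a rho of 0.32 (0.36 with the smooth surface), beyond all block shuffles (both p 0.000999), but genes are not replicates. Taken array by array over 1809 genes, rho averaged -0.35 ± 0.03 (SD, n = 4) in vehicle and -0.30 ± 0.01 (SD, n = 4) in PAC, nearer 0 in PAC in all 4 replicate numbers (exact two-sided permutation p 0.0571, the same with the smooth surface), so whether the gradient differed stays open. Gene dosage or growth rate was not tested as an explanation, and no growth rates were used here. A faster-growing culture holds more gene copies near the origin. A mid-log reference that outgrew the biofilms would thus give ratios that rise with distance. The medians of 0.37 near the origin and -0.32 far from it argue against that, with channel A as the biofilm. With the channels the other way they would go with it.

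A further hypothesis was that PAC biofilms lay closer to the planktonic reference by one factor. Slopes of each array on the mean of 3 vehicle arrays averaged 0.99 ± 0.05 (SD, n = 4) for vehicle and 0.92 ± 0.04 (SD, n = 4) for PAC (exact two-sided permutation p 0.0571 over 70 arrangements). PAC 4 (0.98) lay above vehicle 1 (0.93), although PAC was lower within each of the 4 replicate numbers (exact paired permutation p 0.125, the smallest that 4 pairs can give). The spread of log2 ratios across genes (median absolute deviation) was 0.84 to 0.93 in vehicle and 0.73 to 0.81 in PAC arrays, without overlap. That difference in spread was not tested. With 4 arrays a group, a p that misses 0.05 and an overlap of 1 array in the slopes exclude nothing, so the question stays open. Such a factor would lower TnSmu1 in PAC simply because its ratio is high, and scaling the arrays turned that list's median from -0.20 to 0.36. The same factor would raise SMU.941c and SMU.940c (-2.99 and -2.67 in vehicle) and oxidative stress (vehicle median -1.16). It would lower the pyrimidine (0.92) and arginine (0.43) lists. The F-type ATPase (0.45) and competence (-0.33) moved the other way. With scaling SMU.940c and oxidative stress were not past the threshold, while pyrimidine was (median -0.15, adjusted p 0.00399 in camera).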
